A study of Mus musculus with 28 samples.

How the data were processed

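The series holds 28 Agilent one-colour arrays of mouse RNA, each labelled with Cy3 and read in 1 channel. T cells of young BALB/c mice (4 months) and old ones (20 months) were sorted as CD4 or CD8 cells and either kept unstimulated (0 h) or stimulated with plate-bound antibodies against CD3 and CD28 for 4, 12, 24 or 72 h, per the labels. The cells make 20 groups. Each of the 4 groups at 0 h has 3 arrays and each of the 16 stimulated groups has 1. RNA of a time point was pooled from 4 independent sortings and the repeated arrays at 0 h are described as replicates of pools, per the labels, so p-values here may measure technical spread only. The labels conflict on the gate: titles and the growth protocol describe sorted cells with much CD44, whereas the sample descriptions and the series design describe naive cells with little CD44. A further gate marker and 2 other genes that the naming rule picks are not reported here. RNA was extracted with a column kit and amplified and labelled with Agilent's low-input linear amplification kit, per the labels' protocols.

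The intensity values in the scanner files were read from the scans and background-corrected with Agilent Feature Extraction before deposit, per the file headers, and are on a linear scale. The authors name the same software in their processing notes. Version 10.1.1.1 with a G2505C scanner was used for 18 arrays and version 9.5.1.1 with a G2505B scanner for 10 arrays, per the file headers. The series matrix holds log2 values of the same arrays, deposited by the authors, with the software that made them not given in the sources used here. Set against the scanner values, these were scaled to the 75th percentile of each array and centred per probe. Its column medians lay between -0.972 and 0.494, and the reference set used for centring is not known. In 22 of 28 columns the values were those of the array of the same sample. In the other 6, all from stimulated CD8 cells at 4, 12 and 24 h, they were those of another time point of the same age, with a standard deviation of the differences of 0.00104 or less to that other array and of 0.521 to 1.12 to the array of the same label. The scanner files were followed throughout: each stimulated CD8 array correlated best with the CD4 arrays of its own labelled time in 8 of 8 cases.

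In the present work control spots were left out, and spots flagged as non-uniform or as population outliers were set to missing. Repeat spots of a probe were averaged (245 probes were spotted 10 times). Then log2 of the processed signal minus the 75th percentile of its array was taken. Of 41174 probes, 22944 were named by their accession in a RefSeq gene table of assembly GRCm38.p6, 6664 by symbol and 3108 by an older synonym, and 8458 kept the name in the file. That table gave names and gene neighbours only. Coordinates are those of the files, on mm7. Each gene was represented by its brightest probe over the 28 arrays, and genes well above background on at least 3 arrays were kept, 19490 in all. A gene not well above background on any array of a group has only a bound there, written as at least N-fold: the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background. Where only some arrays of the dimmer group were above background the fold is given as measured and is not exact. Folds below are differences of normalized log2 means, written as ratios.

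The number of probes above background lay between 17254 and 28810 per array. CD4 arrays at 12, 24 and 72 h had a 75th percentile of 120.6 to 275 intensity units against 247 to 874.5 for the others, an overlap of the ranges. Their coefficient of variation of repeat spots was 16.44 to 23.41% against 4.016 to 9.923%. The number of arrays limits precision: no group after stimulation has a replicate. Replicate arrays at 0 h had a standard deviation of their log2 differences of 0.460 to 1.262. No pair of replicates at 0 h held identical values.

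Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Old was set against young at 0 h within each cell type, and CD8 against CD4, in a fit of the 12 arrays at 0 h. Each time was set against 0 h in a fit of all 28 arrays with means for cell type and time and an age term per cell type. Old was set against young over the 16 stimulated arrays with a mean per time, and the change of the age difference with stimulation was fitted over all arrays. In all there were 21 comparisons. Age was not tested at a single stimulated time, with 1 array per age. There a list's median was placed among the medians of 10000 random lists matched on expression. Tables were handled with data.table (1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and figures drawn with matplotlib 3.10.9.

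The comparisons, the rule for naming genes and 28 gene lists were fixed before the data were examined. The lists are naive and quiescence genes, memory and effector genes, early activation genes, cytokines and chemokines, cytotoxic effectors, mitosis, DNA replication, ribosome biogenesis, cytosolic ribosomal proteins, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid transport and one-carbon metabolism, interferon response, p53 and senescence, apoptosis regulators, T cell receptor signalling, inhibitory receptors, regulatory T cells, the NF-kB pathway, chaperones and the unfolded protein response, CD4 lineage and CD8 lineage genes, and markers of B cells, myeloid cells, NK cells, erythroid cells and platelets, and innate-like and gamma-delta T cells. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data. Named genes are the 6 largest rises and 6 largest falls past the threshold that have a gene symbol, were above background on every array of the brighter group and did not overlap between groups (after stimulation, same sign in all 4 age pairs), up to 4 members of a list past the threshold with the largest change and up to 2 that missed it with the smallest p, and a fixed set of sort and activation genes. Genes named outside this rule are stated to be so.

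The arrays lie on 13 slides, read in 5 scan batches. Each slide holds 1 cell type and 1 time. At 0 h slide 12 holds 2 young and 2 old CD4 arrays, slide 4 the third pair, slide 13 likewise 2 and 2 CD8 arrays and slide 6 the third pair. After stimulation both ages share a slide, except CD8 cells at 12 h. The whole CD4 time course and its slide 4 pair were read on the older scanner and software. The replicate numbers at 0 h come from the sample titles. In CD4 cells the same-numbered young and old arrays deviated together from their group means, with correlations across genes of 0.55, 0.49 and 0.68 for numbers 1, 2 and 3. Other pairs on one slide had 0.45 and 0.52, so the numbers follow the slides. In CD8 cells the correlations were -0.24, 0.09 and -0.41, and the numbers were not used as pairs.

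The scripts were tested on simulated data before use, with genes shifted by 1 or 2 on the log2 scale. Of genes shifted by 2, the test of age at 0 h recovered 57% in CD4 and 47% in CD8 cells, and of genes shifted by 1 it recovered 9% and 10%, over 18753 genes. For age in stimulated cells it recovered 43% and 41% at 2, and 1% and 1% at 1, over 17888 genes. The test of the difference in age effect between stimulated CD4 and CD8 cells recovered 0%. Simulated noise was independent between arrays, without the slide structure of the real ones, so these shares do not show recovery under slide differences. Alternatives tried were other scalings, background correction, filters on dim probes, another choice among probes, the series matrix, slides and scans as blocks, the replicate number as a block, other sets of arrays in the fit, and each array left out in turn.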

Results

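RNA of sorted CD4 and CD8 T cells of BALB/c mice aged 4 months (young) or 20 months (old) was measured on 28 one-colour arrays. Cells were taken before stimulation and after 4, 12, 24 and 72 h on plates coated with antibodies against CD3 and CD28. These antibodies act on the antigen receptor and its costimulatory receptor. Before stimulation each age and cell type had 3 arrays. After stimulation each had 1 array per time. Between 17254 and 28810 probes were above background per array. The CD4 arrays at 12, 24 and 72 h were noisier than the others, and most of them were dimmer. Errors below are standard errors of the log2 difference.

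In order to check the sorts, genes of the 2 lineages and of the gate were examined at 0 h. Cd8a was 591-fold higher in CD8 than in CD4 cells (log2 9.21 ± 0.20, adjusted p = 1.6e-08, n = 6 per cell type) and Cd8b1 55.5-fold higher, whereas Cd4 was 7.86-fold lower. Between old and young cells Cd4 stood at -0.86 in CD4 cells (adjusted p = 0.26) and Cd8a at -0.10 in CD8 cells (adjusted p = 0.97). The labels conflict on whether the sorted cells were naive or had much CD44. Cd44, a marker of the gate, was 0.12 ± 0.20 apart in CD4 cells (adjusted p = 0.81) and 0.94 ± 0.20 higher in old CD8 cells (adjusted p = 0.048).

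Old CD4 cells were set against young ones at 0 h to ask which transcripts differ with age before stimulation. Mela, a melanoma antigen of endogenous retroviral origin, was 2580-fold higher in old cells (log2 11.33 ± 0.98, adjusted p = 0.0015, n = 3 per age). Only 1 of 3 young arrays was above background for Mela, as for Pla2g5 and Gzmk, so these folds are not exact. Pla2g5, a secreted phospholipase, was 160-fold higher (7.32 ± 0.42, adjusted p = 9.5e-05), and the granzyme gene Gzmk 50.5-fold higher (5.66 ± 0.57, adjusted p = 0.0026). The BMP receptor gene Bmpr1a was 22.1-fold higher. Kcnip3 rose at least 5.34-fold, a bound because it was not well above background in young cells. The deubiquitinase gene Otud3 fell 21.7-fold (-4.44 ± 0.73, adjusted p = 0.021). Lalba (-4.06 ± 0.54), the transcription factor gene Sox4 (6.36-fold) and Coro2b (-2.46 ± 0.46) also fell, as did Lad1 (at least 4.54-fold) and Bgn (at least 2.74-fold). Arrays of the 2 ages did not overlap for these genes.

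Memory and effector genes lay higher as a group in old CD4 cells, with 6 of 40 past the threshold, none lower and 15 when adjusted over the list alone. Among them were Gzmk, the chemokine gene Ccl5 (15.4-fold) and the chemokine receptor gene Cxcr3 (5.65-fold), whereas Nkg7 (2.58, adjusted p = 0.093) missed it. The list's median was 0.79 (adjusted p = 7.5e-09), and adjusted p = 0.22 with an estimated correlation. B cell markers moved in the same direction, with 5 of 23 higher (12 adjusted over the list alone) and a median of 1.15: Ms4a1 was 10.3-fold higher, Pax5 2.65 ± 0.40 and Blnk 2.46 ± 0.46 (list adjusted p = 1.7e-08, and adjusted p = 0.29 with an estimated correlation). Of 37 cytokine genes 4 rose, among them Ccl5, Il4 (13.6-fold), Xcl1 and Csf1, with a list adjusted p = 0.1. The interferon response list had 3 of 48 higher, Ly6a (7.23-fold), Gbp3 and Iigp1, and Mx2 at -0.83 (adjusted p = 0.097). Its median was 0.19 (adjusted p = 0.035, and adjusted p = 0.75 with an estimated correlation). The cytotoxic list had 1 of 19 higher (4 adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.29 with an estimated correlation). Among CD8 lineage genes 2 of 16 rose (adjusted p = 0.024, and adjusted p = 0.54 with an estimated correlation). Erythroid and platelet markers went the other way, with a median of -0.59 and 1 of 13 lower, the platelet gene Pf4 (adjusted p = 0.024, and adjusted p = 0.22 with an estimated correlation).

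Within the other lists single genes rose in old CD4 cells without a shift of the group. They were the inflammatory caspases Casp1 (8.92-fold) and Casp4 (6.63-fold), the asparagine synthetase gene Asns (5.47-fold), the polymerase gene Pole (1.72-fold), the lactate transporter gene Slc16a1 (1.86-fold) and Pdk1 (1.77-fold), and Nt5e and Socs2 of the regulatory T cell list. Imp4 of the ribosome biogenesis list (-0.88 ± 0.18) and Ikbke of the NF-kB list (-1.10 ± 0.17) fell. These 7 lists had adjusted p from 0.092 to 0.98. No member passed among naive genes (24, median -0.30, adjusted p = 0.12; Dapl1 -1.58, adjusted p = 0.064), mitosis genes (49, adjusted p = 0.11), ribosomal proteins (66, adjusted p = 0.53), oxidative phosphorylation (63, adjusted p = 0.54), cholesterol synthesis (25, adjusted p = 0.27), p53 (30, adjusted p = 0.71), T cell receptor signalling (39, adjusted p = 0.54), inhibitory receptors (12, adjusted p = 0.27) or early activation (28, adjusted p = 0.78), as tested with limma. The same holds for chaperones (34, adjusted p = 0.54), CD4 lineage genes (12, adjusted p = 0.24), and markers of myeloid cells (31, adjusted p = 0.55), NK cells (13, adjusted p = 0.81) and innate-like T cells (8, adjusted p = 0.34). These absences are for the fit without slide as a block. With that block 4422 genes passed, and the list members among them were not counted.

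In all, limma called 333 genes between old and young CD4 cells, 234 higher and 99 lower in old. With the replicate number as a block it called 158, 122 higher and 36 lower, of which 110 were among the 333. The numbers follow the slides in CD4 cells but not in CD8 cells, whose arrays share the estimate of the spread. This count thus does not show what pairing the CD4 arrays alone gives. With slide as a block limma called 4422, 2112 higher and 2310 lower, and those included all 333. The memory list's median was 0.81 on slide 12 and 0.69 on slide 4. Under the slide block the memory list had adjusted p = 9.9e-09 and the B cell list adjusted p = 2.8e-05. The interferon and cytotoxic lists (adjusted p = 0.08 each), CD8 lineage genes (adjusted p = 0.087) and erythroid and platelet markers (adjusted p = 0.062) missed the threshold under that block. Mitosis genes passed it under the replicate block (adjusted p = 0.0082). The B cell median was 1.80 on slide 12 and 0.25 on slide 4. Scaling to the median of each array left 74 genes, 91.9% of them higher against 70.3% of the 333. Without young replicate 1 there were 28, and without young replicate 3 there were 581.

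**Figure D1:**
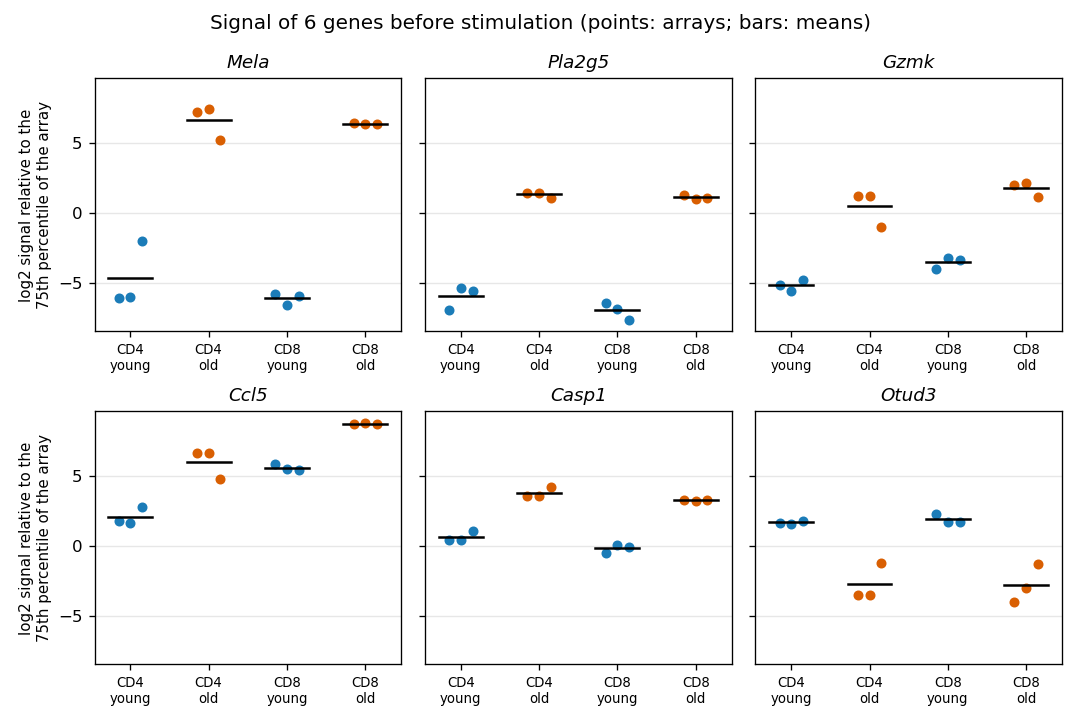
Log2 signal relative to the 75th percentile of the array (vertical axis) for 6 genes at 0 h in young and old CD4 and CD8 cells; each point is 1 array and each bar the mean of 3. Mela, Pla2g5, Gzmk, Ccl5 and Casp1 lie higher and Otud3 lower on every old array than on every young array of the same cell type, with old Mela at 5.26 to 7.45.

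Old and young CD8 cells were compared in the same way. Mela rose at least 2410-fold (adjusted p = 0.00029, n = 3 per age), and Pla2g5 at least 63.0-fold (adjusted p = 3.5e-05), both not well above background in young cells. Kcnip3 rose 48-fold (5.59 ± 0.55), Gzmk 39.5-fold (5.30 ± 0.57), the enkephalin precursor gene Penk 36.5-fold (5.19 ± 0.52) and Bst1 at least 15.5-fold. Otud3 fell 26.1-fold (-4.70 ± 0.73, adjusted p = 0.0092). Nhsl1 (-3.24 ± 0.33), the receptor gene Gprc5b (-3.18 ± 0.28), Arhgap29 (at least 3.92-fold), the transporter gene Abcb11 (at least 3.96-fold) and Kcnj16 (at least 2.15-fold) were also lower.

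Effector genes rose as a group in old CD8 cells. Of 40 memory and effector genes 13 rose and none fell (22 adjusted over the list alone), with a median of 1.35 (adjusted p = 7.4e-21, and adjusted p = 0.03 with an estimated correlation). Gzmm was 21.3-fold higher, S100a6 15.8-fold and the death ligand gene Fasl 12.2-fold, whereas Klrk1 (2.71, adjusted p = 0.058) and Ifng (2.90 ± 0.70, adjusted p = 0.072) missed the threshold. The cytotoxic list had 5 of 19 higher, with Gzmb at 19.1-fold (adjusted p = 2.5e-08, and adjusted p = 0.03 with an estimated correlation). The cytokine list had 4 of 37 higher (11 adjusted over the list alone): Ccl5 (8.98-fold), Tnfsf14 (3.77-fold), Tnf (2.01-fold) and Csf2 (at least 3.42-fold), with adjusted p = 2.8e-08, and adjusted p = 0.047 with an estimated correlation. Among inhibitory receptors 2 of 12 rose, Lag3 (9.59-fold) and Pdcd1 (4.52-fold), and 6 when adjusted over the list alone (adjusted p = 5.8e-05, and adjusted p = 0.047 with an estimated correlation). CD8 lineage genes had 3 of 16 higher, including the cytokine receptor chain gene Il2rb (3.4-fold, list adjusted p = 1.1e-07, and adjusted p = 0.047 with an estimated correlation). Apoptosis regulators had 4 of 31 higher, led by Casp4 (13.1-fold) and Casp1 (10.8-fold), with adjusted p = 0.0071, and adjusted p = 0.047 with an estimated correlation.

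Interferon response genes were higher too, with 8 of 48 past the threshold (15 adjusted over the list alone): Oas1a (8.3-fold), Ifi44 (6.92-fold), Cxcl9 (5.91-fold) and Oasl2 (at least 3.6-fold). The median was 0.38 (adjusted p = 1.1e-11, and adjusted p = 0.067 with an estimated correlation). The mitosis list had a median of 1.20 with 1 of 49 higher, Prc1 (3.2-fold), and 1 lower, the phosphatase gene Cdc25b (-1.21 ± 0.18), with adjusted p = 2.3e-08, and adjusted p = 0.29 with an estimated correlation. The DNA replication list had no member past the threshold (3 adjusted over the list alone, adjusted p = 1.6e-05, and adjusted p = 0.18 with an estimated correlation). Naive genes had a median of -0.37 with none of 24 past it (Dapl1 -1.45, adjusted p = 0.081; list adjusted p = 0.00062, and adjusted p = 0.12 with an estimated correlation). The cell cycle inhibitors Cdkn2a, Cdkn2b and Cdkn1a rose at least 2.06-fold, 2.82-fold and 1.66-fold, and Phlda3 rose 4.14-fold, in a p53 and senescence list that did not shift (adjusted p = 0.21). Zbtb7b, the regulator of CD4 lineage choice, rose 4.64-fold, while Ctsl (2.62-fold) and Trat1 (2.72-fold) of the same list fell (list adjusted p = 0.57). Markers of several other cells lay higher in the same samples. The B cell median was 1.35 with Cd22 17.9-fold and Cd72 2.05-fold higher (12 of 23 adjusted over the list alone; adjusted p = 6.2e-09, and adjusted p = 0.12 with an estimated correlation). The myeloid median was 0.85 with none of 31 past the threshold (adjusted p = 5.8e-05, and adjusted p = 0.43 with an estimated correlation), and the NK cell median was 0.70 (adjusted p = 0.022, and adjusted p = 0.41 with an estimated correlation). Innate-like T cell markers had a median of 0.66 (adjusted p = 0.024, and adjusted p = 0.24 with an estimated correlation). Erythroid and platelet markers had a median of -0.51, with 1 of 13 lower, Car2 (list adjusted p = 0.091).

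These were among 421 genes that limma called in old CD8 cells, 322 higher and 99 lower. With slide as a block it called 1865, 1091 higher and 774 lower, including all 421. The memory median was 1.61 on slide 13 and 1.01 on slide 6, and the B cell median 1.81 and 0.27. Other lists stood apart on slide 13 only, with medians on the 2 slides of 1.39 and -0.07 for mitosis, 0.31 and -0.06 for DNA replication, and 1.51 and 0.01 for myeloid markers. Under the block the memory list had adjusted p = 2.2e-18 and the B cell list adjusted p = 2.1e-06, and oxidative phosphorylation passed too (adjusted p = 0.044). Median scaling left 262 genes, and leaving out old replicate 1 left 173.

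To ask whether the age difference depends on the cell type, the 2 differences were tested against each other. Of the genes called at 0 h, 103 were higher in old cells of both types (3.87 for independent lists) and 8 lower in both (0.503). Both calls use the same estimate of each gene's spread, so the lists are not independent and part of the overlap can come from that. A gene called in both types had opposite directions in 1 of 112 cases. The difference itself passed for 10 genes, each with the more positive value in CD8 cells, and these are named after their values were seen: Lhfp (5.22 ± 0.52, adjusted p = 0.011), Slc5a11 (3.61 ± 0.36), Gzmm (3.58 ± 0.37), Fasl (3.24 ± 0.30), Fn3k (3.04 ± 0.38), Zbtb7b (2.98 ± 0.33), Apobr (2.74 ± 0.35), Phlda3 (2.68 ± 0.30), Hs3st3b1 (2.19 ± 0.25) and Tafa3 (2.03 ± 0.23, adjusted p = 0.013). The interferon list differed with no gene of its own past the threshold (adjusted p = 0.023, and adjusted p = 0.81 with an estimated correlation), and missed the threshold under the slide block (adjusted p = 0.065). With slide as a block 2594 genes differed, 1333 more positive in CD8 cells and 1261 less, including all 10. With median scaling or the replicate number as a block, limma called 0 genes, where the main setting had 2226 at an unadjusted p under 0.05. In CD8 cells the replicate numbers do not follow the slides.

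CD8 cells were compared with CD4 cells at 0 h, over both ages. Beside Cd8a and Cd8b1, the granule protease gene Gzmm was 46.7-fold higher in CD8 cells (5.55 ± 0.18, adjusted p = 2.3e-07, n = 6 per type), Nkg7 45.6-fold (5.51 ± 0.47), the potassium channel gene Kcnj8 42.3-fold (5.40 ± 0.29) and Wdr95 73.9-fold (6.21 ± 0.50). Lower in CD8 cells were the prostacyclin receptor gene Ptgir (55.1-fold), P4ha2 (at least 22.3-fold), the IL-33 receptor gene Il1rl1 (26.2-fold), Pdlim4 (25.8-fold), Foxp3, which specifies regulatory T cells (21.5-fold, -4.43 ± 0.26), and St8sia6 (21.1-fold). Of 16 CD8 lineage genes 15 were higher and 1 lower (adjusted p = 6.7e-17, and adjusted p = 0.0083 with an estimated correlation). Of 12 CD4 lineage genes 6 were lower, among them Zbtb7b (13.9-fold), Trat1 (13.3-fold) and Cd40lg (at least 4.04-fold), with adjusted p = 6e-07, and adjusted p = 0.0083 with an estimated correlation. In the regulatory T cell list 10 of 15 were lower and 1 higher, with Gpr83 at 17.6-fold, Il2ra at 12.8-fold and Socs2 at 10.2-fold (adjusted p = 5.9e-10, and adjusted p = 0.0083 with an estimated correlation).

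Memory genes were higher in CD8 cells for 20 of 40 and lower for 2, with Ly6c1 at 34.3-fold and Cxcr6 at 24.3-fold (adjusted p = 5.7e-11, and adjusted p = 0.06 with an estimated correlation). Cytotoxic genes were higher for 9 of 19 with 1 lower, such as Ctsw (15.9-fold; adjusted p = 4e-05, and adjusted p = 0.06 with an estimated correlation). Mitosis genes were higher for 10 of 49, led by Racgap1 (11.1-fold; adjusted p = 2.6e-06, and adjusted p = 0.47 with an estimated correlation). DNA replication genes were higher for 14 of 52 with 1 lower, led by Mcm10 (3.97-fold; adjusted p = 6.7e-06, and adjusted p = 0.23 with an estimated correlation). Ribosomal proteins were higher for 11 of 66 (adjusted p = 7.2e-06, and adjusted p = 0.48 with an estimated correlation). Cholesterol synthesis went the other way, with 9 of 25 lower and 1 higher, among them Sqle (3.83-fold) and Cyp51 (2.54-fold), with adjusted p = 0.00024, and adjusted p = 0.23 with an estimated correlation. B cell markers were also higher, for 9 of 23 (Cd22 8.16-fold, Cd79b 4.69-fold; adjusted p = 6.5e-05, and adjusted p = 0.36 with an estimated correlation). NK cell markers were higher for 4 of 13 (Eomes 15.1-fold; adjusted p = 0.00037, and adjusted p = 0.3 with an estimated correlation). In all, 2650 genes were called, 1695 higher and 955 lower in CD8 cells. Each slide holds 1 cell type. With slide as a random block 265 were called, and with median scaling 1545, of which 47.9% were higher against 64% of the 2650.

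The response to stimulation was followed by setting each time against 0 h. Each slide holds 1 time, so changes with stimulation cannot be told apart from slide differences. In CD4 cells the slide 12 arrays at 0 h were read on the G2505C scanner and all stimulated arrays on the G2505B scanner. In CD4 cells at 4 h (2 arrays against 6) the cytokine gene Il2 rose 681-fold (9.41 ± 0.78, adjusted p = 8.3e-08), Il3 at least 261-fold, the stress transcription factor gene Atf3 462-fold, the glutathione-degrading enzyme gene Chac1 433-fold, the branched-chain aminotransferase gene Bcat1 424-fold (8.73 ± 0.51) and Sema7a 326-fold. Cd69 rose 22.1-fold, Il2ra 17.7-fold, Ifng 16.4-fold, Gzmb 13.4-fold and Myc 12.5-fold, and the proliferation marker gene Mki67 was at 0.45 ± 0.61 (adjusted p = 0.65). Lrrc75b fell 84.0-fold, Slc16a5 45.4-fold, the Notch modulator gene Dtx1 41.3-fold (-5.37 ± 0.34), Fcgrt at least 25.6-fold, Eya2 at least 13.9-fold and Cd163 at least 8.76-fold. Early activation genes rose for 24 of 28, including the transcription factor gene Irf4 (241-fold) and the costimulatory receptor gene Tnfrsf9 (76.7-fold), with adjusted p = 1.1e-17, and adjusted p = 0.00085 with an estimated correlation. Ribosome biogenesis genes rose for 46 of 49 (Noc3l 7.62-fold; adjusted p = 3.2e-22, and adjusted p = 0.014 with an estimated correlation). Amino acid and one-carbon genes rose for 23 of 25 (Asns 46.0-fold, Psat1 23.5-fold; adjusted p = 1.1e-17), cytokines for 28 of 37 (adjusted p = 3.1e-15) and NF-kB genes for 19 of 27 with 3 lower (Rel 25.0-fold; adjusted p = 2.4e-08). These 3 lists also passed with an estimated correlation. Cholesterol synthesis rose for 16 of 25 with 3 lower (Idi1 14.4-fold; adjusted p = 0.0052, and adjusted p = 0.24 with an estimated correlation) and chaperones for 23 of 34 with 1 lower (adjusted p = 4.2e-06, and adjusted p = 0.12 with an estimated correlation). Naive genes fell for 15 of 24 and rose for 4, with Igfbp4 19.8-fold, Pik3ip1 9.89-fold and S1pr1, the receptor that guides exit from lymph nodes, 9.52-fold lower (adjusted p = 0.0067, and adjusted p = 0.15 with an estimated correlation). Interferon response genes rose for 15 of 48 with 1 lower (Cxcl9 14.1-fold; adjusted p = 0.016, and adjusted p = 0.84 with an estimated correlation). This shift rests on the old array at 4 h, without which the list turned its direction (adjusted p = 0.97).

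At 12 h in CD4 cells Il2 was 1110-fold higher (10.11 ± 0.78), Il3 at least 241-fold, the cysteine synthesis gene Cth at least 143-fold, Bcat1 371-fold, Chac1 339-fold and Atf3 336-fold. Scg5 was 129-fold lower, Armc3 92.4-fold, the migration gene Elmo1 66.8-fold, the heat shock gene Hspa1a 62.9-fold, the Wnt pathway gene Axin2 at least 51.1-fold and Ampd1 at least 31.5-fold. Gzmb rose 52.1-fold, Ifng 42.2-fold, Il2ra 11.9-fold, Myc 8.37-fold and Cd69 4.92-fold, with Mki67 at -0.39 (adjusted p = 0.65). DNA replication genes now rose for 35 of 50 with 2 lower (Orc1 52.4-fold, Mcm10 28.2-fold; adjusted p = 2.1e-07, and adjusted p = 0.31 with an estimated correlation). Oxidative phosphorylation rose for 40 of 61 (Cycs 4.39-fold; adjusted p = 5.7e-07, and adjusted p = 0.31 with an estimated correlation) and glycolysis for 15 of 22 (Hk2 123-fold; adjusted p = 1.4e-05, and adjusted p = 0.15 with an estimated correlation). Naive genes fell for 14 of 24 and rose for 3 (S1pr1 26.1-fold, the IL-7 receptor gene Il7r 17.3-fold; adjusted p = 2.7e-05, and adjusted p = 0.033 with an estimated correlation). At 24 h Il2 was 420-fold higher, Atf3 388-fold, Cth at least 196-fold, Il3 at least 153-fold and Gls2 at least 114-fold, with the thyroglobulin gene Tg also among the 6 largest rises. Scg5 was 94.3-fold, Eldr 93.5-fold and Hspa1a 83.5-fold lower. The spots of Ptma, Trnt1 and Rps24 on the old CD4 array at this time lay over 4 (log2) below those on every other CD4 array, so their falls rest on 1 array. Mitosis genes rose for 43 of 47 with 3 lower and a median of 4.66 (the spindle checkpoint gene Bub1b 138-fold, the separase gene Espl1 109-fold; adjusted p = 6.5e-16, and adjusted p = 0.088 with an estimated correlation). DNA replication genes rose for 46 of 51 (Mcm10 242-fold, Cdc6 204-fold; adjusted p = 5.8e-18, and adjusted p = 0.061 with an estimated correlation), and Mki67 rose 18.3-fold. Gzmb rose 141-fold, Il21 112-fold, Lag3 136-fold, Il2ra 39.5-fold, Ifng 22.6-fold, Myc 4.68-fold and Cd69 2.5-fold. Naive genes fell for 18 of 24 with 4 higher (adjusted p = 2.6e-06, and adjusted p = 0.03 with an estimated correlation).

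At 72 h in CD4 cells Serpinf1 rose 1310-fold (10.36 ± 0.95), the cell cycle inhibitor gene Cdkn1a 1080-fold (10.07 ± 0.68), Slco4a1 931-fold, Gzmb 882-fold (9.78 ± 1.06) and the lipoprotein receptor gene Vldlr at least 541-fold. Tg was again among the 6 largest rises, and Il2 was 19.1-fold higher. Il2ra rose 22.8-fold, Mki67 14.2-fold, Ifng 5.17-fold, Myc 3.31-fold and Cd69 2.44-fold. The adhesion receptor gene Cd44 rose 4.35-fold. Glycolysis genes rose for 20 of 22 with a median of 2.81 (the lactate exporter gene Slc16a3 240-fold, Aldoc 101-fold; adjusted p = 3.5e-12, and adjusted p = 0.051 with an estimated correlation). Mitosis genes rose for 42 of 47 (adjusted p = 2.8e-15, and adjusted p = 0.11 with an estimated correlation), and p53 and senescence genes for 17 of 29 with 2 lower (adjusted p = 0.00017, and adjusted p = 0.053 with an estimated correlation). The largest falls were of transcripts of other blood cells: the neutrophil gene S100a9 (at least 110-fold), the lysozyme gene Lyz2 (at least 124-fold), the immunoglobulin genes Igh-VJ558 (322-fold) and Jchain (at least 81.3-fold) and the globin gene Hbb-bt (191-fold), with Ampd1 at least 29.6-fold. Myeloid markers fell for 16 of 31 with 1 higher (adjusted p = 4.2e-05, and adjusted p = 0.44 with an estimated correlation) and B cell markers for 10 of 23 with 2 higher (adjusted p = 0.031, and adjusted p = 0.52 with an estimated correlation). Over the 4 times limma called 6230 genes at 4 h (3046 higher, 3184 lower), 7869 at 12 h (4685 and 3184), 8626 at 24 h (4846 and 3780) and 7512 at 72 h (4269 and 3243). With slide as a random block the counts were 3341, 4879, 5699 and 4377. The median of all genes stood at 0.26 at 12 h and 0.21 at 72 h, to which the changes at these times are relative.

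**Figure D2:**
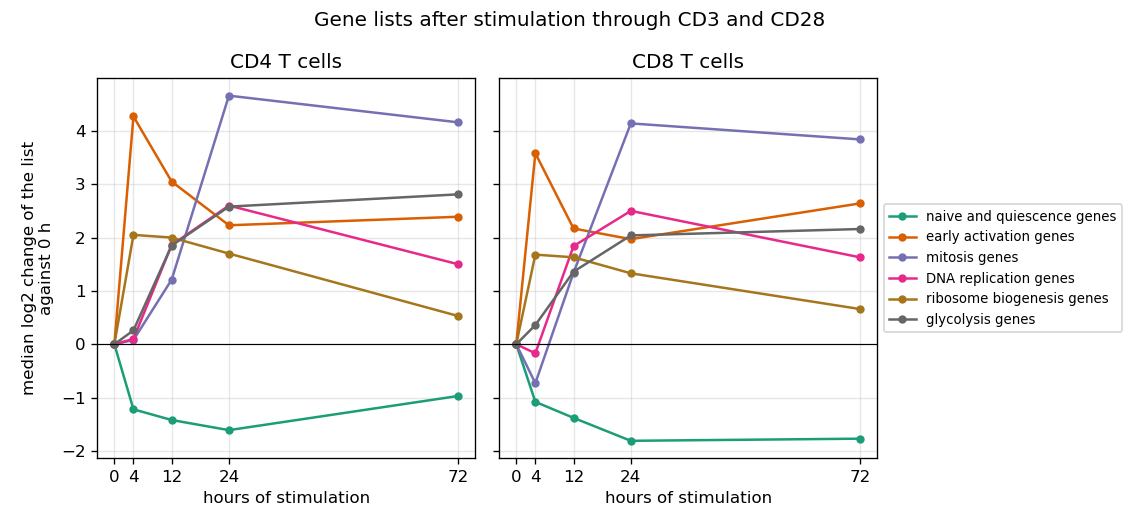
Median log2 change against 0 h (vertical axis) of 6 gene lists by hours of stimulation (horizontal axis) in CD4 cells (left) and CD8 cells (right); lines join the medians over list members, from 2 arrays per time and 6 at 0 h. Early activation genes peak at 4 h (4.27 and 3.58) and mitosis genes at 24 h (4.66 and 4.14), while naive genes stay below 0 throughout.

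In CD8 cells at 4 h Il2ra rose 266-fold (8.05 ± 0.29, adjusted p = 2.3e-12), Irf4 249-fold, Chac1 238-fold, Acod1 163-fold, the cardiac troponin gene Tnnt2 at least 111-fold and Il3 at least 48-fold. Il2 rose 66.9-fold, Ifng 36.3-fold, Gzmb 27.7-fold, Cd69 13-fold and Myc 6.96-fold, with Mki67 at -1.12 (adjusted p = 0.2). Lrrc75b fell 135-fold, Dtx1 52.6-fold, Fcgrt 32.2-fold, Ifitm10 31.7-fold, Ampd1 at least 29.6-fold and S1pr5 at least 22.2-fold. Early activation genes rose for 21 of 28 (adjusted p = 4.5e-14), ribosome biogenesis genes for 45 of 49 (adjusted p = 3.3e-19), amino acid and one-carbon genes for 22 of 25 (adjusted p = 1.4e-15), cytokines for 21 of 37 (adjusted p = 5.7e-09) and NF-kB genes for 18 of 27 with 1 lower (adjusted p = 2.9e-08). All 5 passed also with an estimated correlation. Mitosis genes rose for 2 of 49 and fell for 10, with Kif23 12.4-fold and Racgap1 7.31-fold lower (adjusted p = 0.0032, and adjusted p = 0.65 with an estimated correlation). At 12 h Chac1 was 256-fold, Il2ra 191-fold, Bcat1 128-fold and Gzmb 105-fold higher, Cth at least 57.0-fold, Ccl1 at least 44.6-fold and Il3 at least 35.8-fold. Ifng rose 26.1-fold, Il2 15.4-fold and Myc 2.68-fold, with Cd69 at 1.05 (adjusted p = 0.1) and Mki67 at -0.40 (adjusted p = 0.66). DNA replication genes rose for 40 of 52 with 1 lower (adjusted p = 4.2e-14, and adjusted p = 0.11 with an estimated correlation). Cholesterol synthesis rose for 17 of 25 (Sqle 10.6-fold; adjusted p = 1.7e-07, and adjusted p = 0.034 with an estimated correlation). Naive genes fell for 15 of 24 (adjusted p = 3.3e-07, and adjusted p = 0.016 with an estimated correlation). The largest falls were of the myeloid genes Lyz2 (137-fold), Plbd1 (117-fold), Lyz1 (at least 34.4-fold) and Chil5 (at least 18.6-fold) and of Ampd1 (at least 22.8-fold), and that of Sptbn1 rests on a lost spot.

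At 24 h in CD8 cells the granzyme genes Gzmb and Gzmd rose 222-fold each, Il2ra 205-fold, Chac1 204-fold, Slc7a3 197-fold and Cth at least 184-fold, and Mki67 18.5-fold. Ifng was 30.0-fold and Il2 9.0-fold higher, with Myc at 0.62 (adjusted p = 0.053) and Cd69 at 0.49 (adjusted p = 0.48). DNA replication genes rose for 51 of 52 with a median of 2.50 (adjusted p = 5.9e-24, and adjusted p = 0.03 with an estimated correlation) and mitosis genes for 43 of 49 (Bub1b 72.9-fold; adjusted p = 1.9e-23, and adjusted p = 0.036 with an estimated correlation). Glycolysis rose for 19 of 22 (Slc16a3 45.4-fold; adjusted p = 8.7e-10, and adjusted p = 0.03 with an estimated correlation) and cholesterol synthesis for 19 of 25 (adjusted p = 7.1e-09, and adjusted p = 0.03 with an estimated correlation). Falling groups were T cell receptor signalling for 19 of 39 (Pag1 7.99-fold, Cd3g 3.23-fold; adjusted p = 4.8e-05, and adjusted p = 0.03 with an estimated correlation), naive genes for 18 of 24 (S1pr1 47.5-fold; adjusted p = 9.5e-10), and interferon response genes for 25 of 48 with 5 higher (Oas2 23.6-fold, Rsad2 at least 9.02-fold; adjusted p = 6.7e-07, and adjusted p = 0.29 with an estimated correlation). Beside them B cell markers fell for 17 of 23 (Jchain at least 139-fold; adjusted p = 7.2e-09, and adjusted p = 0.093 with an estimated correlation). Myeloid markers fell for 20 of 31 (Lyz2 at least 486-fold, S100a9 318-fold; adjusted p = 1.1e-07, and adjusted p = 0.29 with an estimated correlation) and NK cell markers for 4 of 13 (adjusted p = 0.0043, and adjusted p = 0.28 with an estimated correlation). At 72 h the secreted cytokine-like gene Spp1 rose 2290-fold (11.16 ± 0.73), Gzmd 477-fold, Cdkn1a 442-fold, Csf2 410-fold, Gzmb 389-fold and Ifng 28.4-fold, Cth at least 223-fold, Ccdc184 at least 202-fold and P4ha2 at least 143-fold. Il2ra rose 242-fold, Mki67 16.8-fold and Cd44 2.79-fold, and Cd8a fell 2.4-fold. Il2 was at 0.95 ± 0.78 (adjusted p = 0.4), Myc at 0.51 (adjusted p = 0.12) and Cd69 at 0.76 (adjusted p = 0.25). Glycolysis rose for 21 of 22 (Slc16a3 127-fold; adjusted p = 2.9e-13, and adjusted p = 0.013 with an estimated correlation) and mitosis genes for 44 of 49 (adjusted p = 5.6e-22, and adjusted p = 0.049 with an estimated correlation). Interferon genes fell for 18 of 48 with 2 higher (Ifit1 11.2-fold; adjusted p = 3.3e-07, and adjusted p = 0.22 with an estimated correlation). The immunoglobulin genes Igh-VJ558 (336-fold) and Iglv1 (266-fold), Lyz2 (at least 269-fold), S100a9 (at least 185-fold) and Pirb (148-fold) fell most. Limma called 5290, 5868, 6440 and 5443 genes at the 4 times (2763, 3107, 3125 and 2653 higher), and 2542, 3853, 3597 and 2624 with slide as a random block.

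Many genes were called in both cell types at the same time: at 4 h 2067 rose in both (432 for independent lists) and 1975 fell (413), and at 72 h 1827 rose (576) and 1568 fell (467). These calls too share the estimate of each gene's spread. The test of the difference in response passed for 12 genes at 4 h (4 more positive in CD8 cells, 8 less), 242 at 12 h (91 and 151), 929 at 24 h (373 and 556) and 1573 at 72 h (603 and 970). Genes named here were chosen after their values were seen. At 4 h Il2ra rose more in CD8 cells (difference 3.91 ± 0.41, adjusted p = 0.00023) as did the cytokine signalling inhibitor gene Cish (2.30 ± 0.39), whereas Il21 (-6.64 ± 0.88), the growth factor gene Areg (-5.41 ± 0.67) and the phosphatase gene Dusp6 (-3.08 ± 0.43) rose less. At 12 h Il2 (-6.17 ± 1.11, adjusted p = 0.012) and Il22 (-4.50 ± 0.79), and at 24 h Il21 (-7.82 ± 0.88) and Il2 (-5.54 ± 1.11), were less positive in CD8 cells, and Elmo1 (5.90 ± 0.70 and 5.01 ± 0.70) more. At 72 h the B cell adaptor gene Blnk (-5.98 ± 0.67), Ly6c1 (-5.54 ± 0.75) and Il10 (-4.99 ± 1.12) were less positive. Of 28 lists 17 were called at 4 h, all less positive in CD8 cells, and 0 with an estimated correlation. They included interferon response genes (adjusted p = 7.5e-09), mitosis genes (adjusted p = 8.1e-06) and cytokines (2 of 37 lower, adjusted p = 3e-05). The interferon rise in CD4 cells at 4 h rests on the old array of that time, so this list's difference may rest on it too. At 12, 24 and 72 h 3, 4 and 5 lists were called, in both directions at 24 and 72 h, among them B cell markers at 72 h (7 of 23 lower, median -2.24; adjusted p = 2e-05, and adjusted p = 0.54 with an estimated correlation). Cell types lie on different slides. With slide as a random block 1, 5, 13 and 55 genes were called at the 4 times, and with only the 0 h arrays scanned with the time course 0, 1, 20 and 149, against 1498, 3499, 4300 and 4499 at an unadjusted p under 0.05 in the main setting. Under median scaling 70.6% of the calls at 24 h and 66.9% at 72 h were more positive in CD8 cells, against 40.2% and 38.3%.

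Age was then compared over the stimulated arrays, with each time as a pair of ages. In stimulated CD4 cells Mela was 304-fold higher in old cells (8.25 ± 0.38, adjusted p = 8.2e-05, n = 4 per age) and Pla2g5 at least 29.7-fold (adjusted p = 0.011). The type 2 cytokine genes Il5 (59.0-fold), Il4 (23.8-fold) and Il9 (10.5-fold), the kinase subunit gene Prkar2a (19.3-fold), the chemokine receptor gene Ccr2 (5.03-fold) and the inhibitory receptor gene Havcr2 (5.99-fold) rose, and the fatty acid oxidation gene Acads fell 8.87-fold. Il10 (3.87, adjusted p = 0.076) and the type 2 regulator Gata3 (2.19, adjusted p = 0.056) missed the threshold. In the cytokine list 3 of 37 rose (12 adjusted over the list alone) with a median of 1.07 (adjusted p = 9.7e-12, and adjusted p = 0.2 with an estimated correlation). The memory list had 1 of 40 higher and 8 adjusted over the list alone (adjusted p = 0.00059, and adjusted p = 0.58 with an estimated correlation). B cell markers had a median of 0.73 with none of 23 past the threshold and 9 adjusted over the list alone (adjusted p = 0.0043, and adjusted p = 0.75 with an estimated correlation). Limma called 22 genes, 20 higher and 2 lower. The count was 1 without either CD4 array at 12 h and 3 without either at 24 h, 50 with median scaling, and 20 with slide in place of time.

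In stimulated CD8 cells Mela rose at least 1330-fold, Pla2g5 57.0-fold, the chemokine gene Ccl1 26.7-fold, Dnah17 24.6-fold, Gzmk at least 18-fold and the cell cycle inhibitor gene Cdkn2a at least 9.23-fold. Otud3 fell 29.9-fold, the phosphatase gene Ptprf 10.5-fold, Acads 9.65-fold, the stem cell factor receptor gene Kit 8.98-fold, Plxdc2 7.52-fold and Mmp14 6.61-fold. Il4 (18.1-fold), Il9 (16.2-fold), S100a6 (9.0-fold), Gzmm (7.15-fold), Cdkn2b (19.6-fold), Casp1 (7.0-fold) and the inhibitory receptor genes Havcr2 (5.3-fold) and Entpd1 (5.27-fold) rose too. The memory list had 4 of 40 higher (16 adjusted over the list alone, adjusted p = 3.9e-11, and adjusted p = 0.18 with an estimated correlation). The interferon list had a median of -0.55 with none of 48 past the threshold and, adjusted over the list alone, 12 lower and 1 higher (adjusted p = 5.6e-08, and adjusted p = 0.63 with an estimated correlation). Mitosis genes had a median of 0.65 with none of 49 past it (adjusted p = 1.3e-08, and adjusted p = 0.63 with an estimated correlation). By time their medians were -0.23, 0.80, 0.29 and 1.67 at 4, 12, 24 and 72 h, and the old array at 72 h had the highest spread of negative controls of all arrays. In all, 80 genes were called, 64 higher and 16 lower. Without the CD8 arrays at 12 h, which lie on different slides for the 2 ages, or with slide in place of time, the count was 31, with median scaling 138, and without either array at 24 h 22.

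Between stimulated CD4 and CD8 cells 14 genes called higher in old cells were shared (0.0657 for independent lists), though both calls use the same estimate of each gene's spread. The difference of the age effect passed for 0 genes with limma, 779 at an unadjusted p under 0.05. The change of the age effect with stimulation passed for 0 genes in CD4 cells (764 at an unadjusted p under 0.05) and for 2 in CD8 cells, named after their values were seen: Ccl1 (5.03 ± 0.74, adjusted p = 0.047) became more positive in old cells and Asns (-3.11 ± 0.47, adjusted p = 0.047) less. With no filter on dim probes that count was 0, as it was without old CD8 replicate 1 or 2, and without old CD8 replicate 3 it was 27. The interferon list shifted in CD8 cells, with 47 of 48 members below 0, a median of -1.04 and 19 lower when adjusted over the list alone (adjusted p = 9.3e-25, and adjusted p = 0.072 with an estimated correlation). At single times no test was run. Old minus young, the interferon median in CD8 cells was -0.43, -0.87, -0.63 and -0.40 at 4, 12, 24 and 72 h, at or below the 0.02 percentile of matched random lists, and in CD4 cells it went from 0.85 at 4 h to -0.86 at 72 h. In CD8 cells it was 0.20 at 12 h under median scaling and 0.16 at 72 h with normexp on median signals, so the direction at these 2 times depends on the processing. In CD4 cells the sign held, but the size moved, to 1.32 at 4 h under median scaling and -0.39 at 72 h with normexp.

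**Figure D3:**
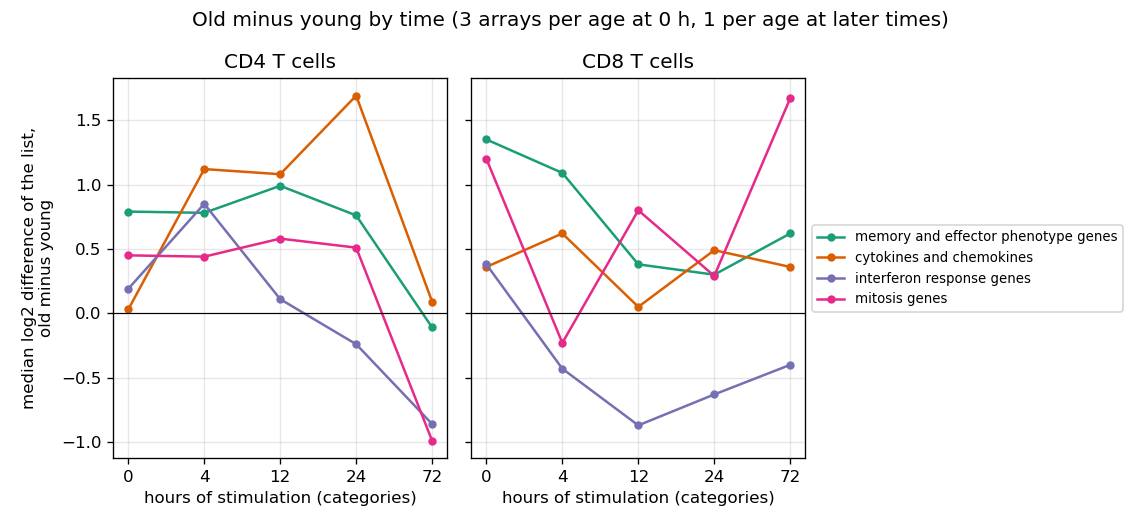
Median log2 difference, old minus young (vertical axis), of 4 gene lists at each time of stimulation (horizontal axis, categories) in CD4 cells (left) and CD8 cells (right); points are medians over list members, from 3 arrays per age at 0 h and 1 per age later. The interferon response median in CD8 cells lies above 0 at 0 h (0.38) and below 0 at each later time under the main scaling, and the memory median lies above 0 throughout except in CD4 cells at 72 h (-0.11).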

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

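Tests of genes with no second probe, of the falls against other cell types, of neighbouring genes, of the share of T cells, of the gate, of bright genes in CD8 cells alone, of the scanner and of slides for the response at 72 h were chosen after the results were seen.

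A test of the difference between groups singled out 6 results. The age difference at 0 h differed between CD4 and CD8 cells for 10 genes, the response to stimulation differed between them for 12, 242, 929 and 1573 genes at 4, 12, 24 and 72 h, and the age difference changed with stimulation in CD8 cells for 2 genes.

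Of all genes 27 were called with the same sign in at least 3 of the 4 age comparisons (0 h and stimulated, CD4 and CD8), among them Mela, Pla2g5, Penk, Naip2 and Hoxc9, which rose, and Otud3, which fell. A sequence variant under the probe was tested with the genes' other probes, and 77.8% of 9 showed the same sign at over 1 (log2). This goes against that explanation for the genes of those probes. Of the genes just named only Penk had such a probe. The other probes of Ptpn13 and Tafa3 had means of 0.94 and 0.48 over the 4 comparisons, against 2.31 and 2.08 for the probes used. A variant stays open for these 2 genes. For 19 of the 27 genes no second probe could be read, so a variant under the probe cannot be told apart from a change of the transcript. Cells of another type in the old sorts were tested on the 2 falls, which lie at 1 locus, and the smallest of the 4 medians was -5.41, more than other cells' RNA could replace. These 2 genes were picked for being called in the same comparisons, and the test says nothing about the genes that rose. A different genetic background of the young and old animals was tested by position: 2 pairs of the genes outside that locus lay within 500 kb of each other, as in 1.9% of random sets, and with no genotypes in the data this cannot be told apart from an effect of age.

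Memory and effector genes lay higher in old cells of both types at 0 h, also within each of the 4 slides, where the smallest median was 0.69, against a slide difference as the cause. A lower share of T cells, raising all other cell types alike, was tested with a permutation test over genes of B cell against erythroid and platelet markers (100000 permutations). These moved apart in CD4 cells (permutation p = 1e-05, the smallest possible) and in CD8 cells (permutation p = 0.00016). The lists were picked after their medians were seen, and the test takes genes as independent, so its p measures no spread between arrays. On slides 12, 4, 13 and 6 the B cell medians were 1.80, 0.25, 1.81 and 0.27, and the erythroid and platelet medians -0.43, -0.70, -0.16 and -0.23. The 2 lists thus did not rise alike, without a test between arrays. The T cell gene Cd3e, named outside the rule, stood at -0.80 in old CD4 cells (95% interval -1.37 to -0.22, limma adjusted p = 0.16). In old CD8 cells it stood at 0.05 (-0.52 to 0.63). A lower share of T cells in the old CD4 sorts was thus not excluded. A rise of certain other cells stays open, since myeloid, NK and innate-like markers also lay higher in old CD8 cells (0.85, 0.70 and 0.66). Memory T cells inside the sorting gate were tested with the gate gene Cd44, which, old minus young, stood at 0.94 in CD8 cells (95% interval 0.48 to 1.39) and at 0.12 in CD4 cells (-0.33 to 0.57). The interval in CD4 cells, from the fit without slide as a block, is too wide and the labels of the gate too contradictory to decide. More memory cells and a change within naive cells with age thus cannot be told apart.

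The response at 72 h differed between CD4 and CD8 cells for 1573 genes. The dim and noisy CD4 arrays were tested by signal: genes above background on all 28 arrays were called 1.73 times as often as the others (10.3% of 9977 against 5.93% of 9265). For CD8 cells alone at 72 h, without those arrays, the ratio was 1.48, so bright genes are called more often in any case, and noisy arrays and a difference of the cell types cannot be told apart. The scanner and software of the CD4 time course were tested as a fixed block, and 1881 genes passed. The block differs only among arrays at 0 h, so this count also reflects how much those arrays spread. The time-course scans alone, with fewer arrays at 0 h, gave 149, so a shift from the scanner was not excluded. With the slides, which hold 1 cell type each, as a random block 55 genes passed, slides and cell types cannot be told apart by design, and a difference between the cell types in how they respond stays open.

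Other splits of the arrays were fitted in the same way. For CD4 against CD8 cells 1 of 100 splits, the real one, gave as many genes (2650, highest other 60), so chance among single arrays can be excluded. Each slide holds 1 cell type, so cell types and slides cannot be told apart there, and with slide as a random block 265 genes passed. For age in stimulated cells the fit pairs ages by time, and the 8 splits that part all pairs are too few for a share under 0.05 (22 genes with highest other 0 in CD4 cells, 80 with highest other 2 in CD8 cells, in each case 1 split). Over all 32 splits, of which the others part fewer pairs, 1 gave as many genes, with highest other 16 and 2. For age at 0 h the 10 splits per cell type are too few for a share under 0.05 (333 with highest other 13 in CD4 cells, 421 with highest other 0 in CD8 cells, in each case 1 split). Chance was not excluded for the difference of the age effect at 0 h (10 genes, 6 of 100 splits, highest other 712, though the splits do not keep the slides, and with slide as a block 2594 genes passed), nor for its change with stimulation in CD8 cells (2 genes, 14 of 100, highest other 612). With 0 genes called every split gives as many, so the splits decide nothing for the difference in stimulated cells (100 of 100, highest other 232) and the change with stimulation in CD4 cells (100 of 100, highest other 969). Splits that call many times the real count point to a structure of the samples, such as the slides.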

How the results depend on the processing

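Alternatives chosen after seeing the data were normexp on median signals, lost spots set to missing, scan batches as a block, the 0 h arrays of the time-course scans alone, slides 12 and 13 alone, and the sets without the dim or unpaired arrays. Of 733 counts over 21 comparisons 536 stayed within 1.5 times of the main count and 197 moved. The cause was not tested, and where arrays were left out the counts moved both up and down. The mean of all probes of a gene, the series matrix values and lost spots set to missing moved no count. A fit on mean signals, fixed beforehand, was not run since 18 of 28 files lack them, and the series matrix was not used for stimulation because of its 6 misplaced columns. In CD4 cells at 72 h 19242 genes had a value to test, against 19490 at 4 h, because flagged spots were set to missing. What the dim arrays limit was not tested. Results below follow the order in which their comparisons stand in the report.

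Median scaling gave for age at 0 h 74 (CD4), 262 (CD8) and 0 (difference), 1545 for CD4 against CD8, 3887 for CD4 at 4 h, 3096 and 3836 for CD8 at 4 and 12 h, 126, 510 and 664 for the response difference at 12, 24 and 72 h, 50, 138 and 2 for age in stimulated CD4 and CD8 cells and its difference, and 2 and 1 for the change of the age effect with stimulation in CD4 and CD8 cells. Quantile normalization gave 17 for the age difference between cell types at 0 h, 439 and 2399 for the response difference at 12 and 72 h, and 3 and 7 for the change with stimulation in CD4 and CD8 cells. Normexp on median signals gave 36 for the age difference between cell types, 3453, 3743 and 8554 for CD8 at 4, 12 and 72 h, 107 and 299 for the response difference at 12 and 24 h, and 35 and 50 for age in stimulated CD4 and CD8 cells.

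With no filter on dim probes there were 116 genes for age in CD4 cells at 0 h, 6 for the age difference, 115, 472 and 1022 for the response difference at 12, 24 and 72 h, and 0 for the change with stimulation in CD8 cells. With probes well above background on at least 14 arrays there were 533, 39 and, for the response difference at 12 h, 462, with 62 for age in stimulated CD4 cells, 1 for the difference in stimulated cells and 6 for the change in CD8 cells. Of 11481 results for named genes 770 lost and 62 gained a call, and none turned its direction with a call in either setting. A further 13 changed sign without a call in either setting. Of 3386 results for lists 99 lost and 31 gained a call. Another 2 turned with a call in 1 of the settings, both with 1 array left out, and 39 changed sign without a call in either. Ribosomal proteins in CD4 cells at 0 h had adjusted p = 0.011 to 0.86 with each array left out, and turned without young CD4 replicate 3 (adjusted p = 0.013). They also changed sign, without a call, under quantile normalization and with slides 12 and 13 alone. Interferon response genes in CD4 cells at 4 h had adjusted p = 2.1e-06 to 0.97, and turned without the old array at 4 h (adjusted p = 0.97). Camera called 231 list results at the preset correlation and 46 with an estimated one.

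The replicate block gave 158 for age in CD4 cells and 0 for the difference, with the spread estimated over both cell types. In CD8 cells, where the numbers are no pairs and not every array correlated best with its own number, it gave 436, of which 278 were among the 421. By replicate number no paired analysis was possible because stimulated groups have 1 array each, and their ages were paired by time in the fit. Slide as a fixed block gave for age 4422, 1865 and 2594. With slide in place of time age in stimulated CD8 cells gave 31, and with time left to the slides the change with stimulation gave 1 (CD4) and 9 (CD8). Slide as a random block gave 265 for CD4 against CD8, for CD4 times 3341, 4879, 5699 and 4377, for CD8 times 2542, 3853, 3597 and 2624, and for the response difference 1, 5, 13 and 55. Scan batches as a fixed block gave 153 for the response difference at 12 h, and 2 and 13 for the change in CD4 and CD8 cells.

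The 0 h arrays of the time-course scans alone gave 3808 for CD4 at 4 h, 2648, 3744 and 3442 for CD8 at 4, 12 and 72 h, and 0, 1, 20 and 149 for the response difference. Fitting 20 group means with ages averaged gave 62, 924 and 1704 at 4, 12 and 24 h. All 28 arrays with separate age terms gave 217 and 285 for age in stimulated CD4 and CD8 cells and 6 for the difference. Slides 12 and 13 alone gave 6133, 5977, 5707 and 9552 for the 4 comparisons at 0 h. Without CD4 at 12 h and CD8 at 72 h age in stimulated cells gave 3 (CD4) and 18 (CD8), and the change in CD8 cells 0. Without CD4 at 12, 24 and 72 h the response difference at 4 h was 29. Without CD8 at 12 h age in stimulated CD8 cells gave 31 and the change in CD4 cells 1.

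With each array left out in turn the counts spanned 28 to 581, 173 to 707 and 0 to 81 for age at 0 h and its difference, 1559 to 3006 for CD4 against CD8, 3495 to 6664, 5099 to 8221, 5273 to 8951 and 5491 to 7734 for CD4 times, 2468 to 5688, 3420 to 6231, 3573 to 6847 and 3086 to 5856 for CD8 times, 1 to 36, 97 to 581, 66 to 1303 and 352 to 1662 for the response difference, 1 to 22, 22 to 112 and 0 to 2 in stimulated cells, and 0 to 15 and 0 to 27 for the change in CD4 and CD8 cells. A lone array left in a group is assumed to vary like the other groups. For age in CD4 cells the count was 84 and 59 without old CD4 replicate 1 or 2, 28, 32 and 581 without young CD4 replicate 1, 2 or 3, 158 and 135 without old CD8 replicate 1 or 2, and 162 and 139 without young CD8 replicate 2 or 3. For age in CD8 cells it was 707 without old CD4 replicate 3, 173 and 178 without old CD8 replicate 1 or 2, and 203 and 197 without young CD8 replicate 2 or 3. For the difference it was 5, 6 and 40 without old CD4 replicate 1, 2 or 3, 3, 0 and 29 without young CD4 replicate 1, 2 or 3, 0, 0 and 81 for old CD8 and 19, 0 and 6 for young CD8. For CD4 against CD8 it was 1631 and 1559 without old CD8 replicate 1 or 2, and 1750 and 1735 without young CD8 replicate 2 or 3. Stimulation counts moved without the time's own array: CD4 3495 (old, 4 h), 5099 (old, 12 h) and 5273 (old, 24 h), and CD8 2468 (young, 4 h), 3420 (old, 12 h), 3806 and 3573 (old and young, 24 h) and 3424 and 3086 (old and young, 72 h). The response difference at 4 h was 1 without old and 36 without young CD4 at 4 h, 21 without either CD4 at 72 h and 3 without old CD8 at 4 h. At 12 h it was 156 and 424 without old CD4 replicate 1 or 3, 152 and 367 without young CD4 replicate 1 or 3, 97 and 581 without old or young CD4 at 12 h, 504 without either CD4 at 72 h, 148 without old CD8 replicate 2 and 120 without young CD8 at 12 h. At 24 h it was 603 without old CD4 replicate 1, 158 without old CD4 at 24 h, 559 and 544 without old CD8 replicate 1 or 2, 587 without young CD8 replicate 3, and 66 and 287 without old or young CD8 at 24 h, and at 72 h it was 352 without old CD8 at 72 h. In stimulated cells leaving out either age of a time gives the same count: for CD4, 1 and 3 without CD4 at 12 or 24 h and 13 and 7 without CD8 at 4 or 24 h, for CD8, 45, 31, 22 and 46 without CD8 at 4, 12, 24 or 72 h, and for the difference 2 without CD4 at 4 h. The change in CD4 cells was 6 without old and 10 without young CD4 replicate 3, 15 without CD4 at 4 h, and 1 and 2 without CD8 at 12 or 72 h. The change in CD8 cells was 0 without CD4 replicates 1 or 2 of either age, CD4 at 12 h, old CD8 replicate 1 or 2, young CD8 replicate 2 or 3, or CD8 at 24 or 72 h, 5 without old CD4 replicate 3 or CD4 at 72 h, 4 without young CD4 replicate 3, 27 without old CD8 replicate 3 and 10 without CD8 at 4 h.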

Other observations

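The comparisons here were chosen after the results were seen. Proliferation and glycolysis genes stood apart between old and young cells late in the response, with 1 array per age and time and no test run. At 72 h the mitosis median, old minus young, was 1.67 in CD8 cells with 49 of 49 members above 0, and the DNA replication median was 1.07 (2.11 with normexp on median signals) with 52 of 52 above 0, both at the 100th percentile of matched random lists. The old CD8 array of this pair stands apart, with 17912 probes above background against 23640 and a spread of negative controls of 4.939 against 1.778, the highest of all arrays, and ribosomal proteins lay lower on it for 66 of 66. In CD4 cells at 72 h the same medians were -0.99 (6 of 41 above 0) and -0.77 (6 of 45 above 0), both at the 0th percentile. Glycolysis genes lay lower in old CD8 cells at 24 h (-0.38) and 72 h (-0.82, 3 of 22 above 0, but 0.50 with normexp on median signals), and in old CD4 cells at 12 h (-0.60) and 24 h (-0.50), but not at 72 h (0.24, 12 of 19 above 0). Cytokine genes lay higher in old CD4 cells at 4, 12 and 24 h (1.12, 1.08 and 1.69) and stood at 0.09 at 72 h (-0.23 under median scaling). The median at 4 h was 0.46 with probes above background on at least 14 arrays and 0.65 with normexp on median signals, and that at 24 h was 1.05 with normexp.

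Among the 27 genes called with one sign in at least 3 age comparisons, the enkephalin precursor gene Penk (2.73 and 5.19 in CD4 and CD8 cells at 0 h, 3.12 and 4.44 stimulated), the inflammasome sensor gene Naip2 (2.10, 2.82, 2.07 and 2.52) and the homeobox gene Hoxc9 (2.83, 2.00, 2.85 and 2.64) were called in all 4. Pla2g5 and Otud3 lie within 100 kb on chromosome 4 and moved in opposite directions.

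The old CD4 array at 24 h had 64 spots over 4 (log2) below those on every other array of the cell type, all bright there, covering 46 fitted genes, and the old CD8 array at 12 h and young CD8 replicate 2 had 30 each.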
